A study of Saccharomyces cerevisiae with 121 samples.

How the data were processed

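The series holds 121 arrays of budding yeast, Saccharomyces cerevisiae, each hybridised with material from a strain in one dye and from a wild-type euploid strain grown in the same way in the other. Most strains are disomes, haploid strains with a second copy of the chromosome named in their label. RNA was measured on 29 arrays and genomic DNA, as comparative genomic hybridisation (CGH), on 92. Per the labels, RNA was extracted with acid phenol and DNA with a Hoffman-Winston preparation. The batch cultures grew in medium without histidine and with G418, and the chemostat cultures were limited for phosphate. Within a growth condition and kind of material, each strain was hybridised once, apart from the label E256X-cup1-UBI4 disome XI, which has an array in each dye orientation. These arrays were averaged as 1 strain by their label, although their marker genes differ, and the value and number of that class rest on the label. The labels do not say whether strains of a class came from separate cultures, so that p-values measure only the spread between these arrays.

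Each array was scanned and its spots were measured with Agilent Feature Extraction, per the file headers, in version 9.1.3.1 for 103 files, 9.5.1.1 for 13 and 10.5.1.1 for 1. Scanner files for 117 arrays on 34 slides were used, with 12512 spots on the 15k format and 43792 on the 44k format. Mean and background signals are given as intensity, a linear brightness, per the file headers. Processed intensity values are background-subtracted, spatially detrended and dye-normalised, by a linear method on the CGH protocol and by linear and lowess steps on the expression protocol, per the file headers. The files also give the log10 of processed Cy5 over processed Cy3 signal per spot, per the file headers. The deposited value table holds log2 ratios of strain over wild type. Its 117 columns with a scanner file equal the scanner log ratio on a log2 scale, with a correlation of 1 and a median difference of at most 0.000255, and the sign is turned in the 43 columns whose labels put the strain in Cy3. The table is not centred: column medians run from -0.368 to 0.257, with a median of -0.014. For these columns the scale and centring are known. The labels give the direction except for XVI-14.2, where the RNA of chromosome XVI argues for the strain in Cy5, as given below. For 4 arrays, the isolates IV-9.1, IV-9.2, V-9.1 and V-9.2, only the value table was used, and these are described separately. The genome build behind the array annotation is not given in the sources used here, so no coordinates are printed.

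Ratios were turned to strain over wild type from the dyes in the labels. The RNA isolate XVI-14.2, whose labels contradict each other on the dye, was left out of the comparisons. Among the CGH arrays with a scanner file, 45 have the strain in Cy5 and 43 in Cy3. The lowest correlation between arrays of one orientation was -0.31 in Cy3, with 1 of 903 pairs under -0.3, and -0.45 in Cy5, with 2 of 990 pairs under it. Directions were kept there, because the labels state the dyes and the strains carry different extra chromosomes. Control spots and outlier-flagged spots were removed, saturated spots were kept, spots of a probe were averaged and genes with several probes took their mean. The arrays name 6256 genes, of which 5756 matched the reference gene table of assembly R64, used for names and gene order. The mitochondrial genome holds 23 of the genes.

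RNA ratios were made with limma 3.58.1 in R 4.3.3 from mean and local background signals by the normexp correction with an offset of 50 and loess within each array. A gene was kept where it was well above background in either channel on a share of at least 0.5 of the arrays of a fit. CGH ratios were made from processed signals and centred on the median of each array, without loess. The other packages were statmod 1.5.0, numpy 2.4.6, pandas 2.3.3, data.table (version 1.17.8) and matplotlib 3.10.9 in Python 3.11.15.

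Signal quality set the precision. A median of 99.99% of probes was well above background on the DNA arrays of each format, 99.0% on the 15k RNA arrays and 93.7% on the 44k RNA arrays. The lowest array reached 90.5%, a DNA array of the 15k format. The median green signal over background ran from 3.68 to 439.2 on the 15k DNA arrays and from 6.61 to 8.44 on the 44k RNA arrays. The median SD between spots of a probe was 0.0572 and 0.0528 on the DNA formats and 0.061 and 0.0661 on the RNA formats, in log2. The highest was 0.91, on the UBP6del-lys2 disome V array. Outlier flags took 85.7% of the spots of the E256X disome IV array. Beyond this, the number of arrays limits the precision.

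Gene tests used limma's lmFit and eBayes with Benjamini-Hochberg adjustment, and an adjusted p under 0.05 was called. Evolved isolates in batch were compared with the parental disome of the same chromosome, with the chromosome as a fixed block that pairs them by their label. The batch disomes were compared with the wild-type self-hybridisation, and the chemostat isolates with 0, since no wild type was hybridised against the chemostat reference. Those fits took the chromosome as a random block (duplicateCorrelation) and set the genes of the named chromosome to missing. The chemostat test leaves out the control's own spread. CGH classes were compared gene by gene with the chromosome as a fixed block and the strain's dye as a term. Single values were compared by exact two-sided sign-flip tests over chromosomes or isolates, or by two-sided permutation tests with 1e+05 resamples.

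Of 25 gene lists, 22 were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation. These were ribosomal protein genes, ribosome biogenesis, proteasome subunits, the ubiquitin system, chaperones, the induced environmental stress response, amino acid biosynthesis under Gcn4, methionine and sulfur assimilation, the phosphate and iron regulons, ergosterol, respiration, glycolysis, hexose transporters, redox defence, a-specific, alpha-specific and mating genes, histones, cell cycle, DNA damage and cell wall. The 3 remaining lists hold engineered, marker and variable-copy loci, which were read as single genes. Of the 39 list calls in the full comparisons, 0 held with the estimated correlation. That test rests on the residual degrees of freedom of each fit, which are few. Within 1 slide it could hardly call any list, so 0 calls there decide nothing.

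A chromosome counted as gained at a median of at least 0.5 and as intermediate from 0.2. Parts of chromosomes were sought by binary segmentation, with at least 10 genes on each side, a difference of at least 0.4 between the sides and a statistic beyond 1000 shuffles of the chromosome. Breaks within 20 genes of an end were counted apart.

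The named genes are the 10 highest and 10 lowest called genes with the same direction in at least 80% of the strain arrays, the 3 members with the smallest p of each called list and the engineered loci. Where no gene was called, these are the 5 with the smallest p, and for DNA the 5 highest and 5 lowest. Ty elements, dubious reading frames without a symbol and the COS, PAU and YRF1 families were counted but not named. In the DNA comparison of evolved isolates, reading frames known only by their systematic name are named too. Groups, tests, lists, this rule and most alternatives were fixed before the data were examined, and 7 alternatives were added later.

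Each fit was tested on simulated data. For evolved against parental disomes, changes of 0.5, 1 and 2 in log2 were recovered for 60.3%, 92.4% and 100% of changed genes, among 6252 genes. Against the wild type in batch, 7.35%, 50% and 89.4% were recovered for the parental and 2.94%, 54.5% and 83.3% for the evolved strains, also over 6252 genes. In the chemostat, 83.8%, 100% and 100% were recovered over 5975 genes, and for disome V 45.6%, 87.9% and 98.5% over 5955 genes. Over 6256 genes, DNA changes of 0.5 and 1 were recovered for 85% and 100% of genes with UBP6del, 62% and 97% with E256X and 99% and 100% with evolved isolates. Simulated gains that reached a chromosome end were found in 100% of 67 chromosomes, and inner ones in 67.2% of 67 by single breaks and 100% by pairs of breaks, with 0 false calls in 66. In the RNA and segment simulations, genes varied independently with a normal spread, without differences between slides. These rates therefore need not hold for the real arrays, where the euploid GFP strain had 8 breaks near chromosome ends.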

Results

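The arrays cover disomic yeast, haploid strains that carry 1 chromosome in a second copy, and derivatives of them. Parental disomes, isolates evolved from them and strains with engineered loci were measured, each against a euploid wild type. RNA was measured in batch culture for 6 parental disomes (V, VIII, IX, XI, XIV and XVI), 9 evolved isolates and 1 wild-type self-hybridisation, all on the 15k format. In phosphate-limited chemostats it was measured for 12 evolved isolates of 7 disomes and the parental disome V, on the 44k format. DNA was measured for 26 evolved isolates with 9 in their label and 2 with 14, which the labels do not explain. The engineered disomes were 12 with GFP, 12 with UBP6del, 10 with E256X, 10 with URA3, 4 with rpn6, 3 with ubp6CA, 1 with lys2 and 1 with both UBP6del and lys2. Strains with cup1-UBI4 made 3 with GFP, 2 labelled E256X and 2 labelled delubp6, which are grouped here with UBP6del. Of the delubp6 strains 1, the library labelled Dis V-delubp6-cup1-UBI4, kept its UBP6 signal at 0.38. Euploid strains with GFP, E256X and UBP6del had 1 array each. UBP6 encodes a deubiquitinating enzyme of the proteasome, RPN6 a proteasome subunit and UBI4 polyubiquitin. Changes are log2 ratios, no strain class has replicate arrays of a strain unless stated, and the number of arrays limits the precision.

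Evolved isolates in batch, 8 against 6 parental disomes paired by chromosome, had lower LEU1 and OAC1 transcripts than the strains they came from. LEU1 (YGL009C), for isopropylmalate isomerase, fell by -1.92 (SE 0.27, adjusted p = 0.0435), a 3.79-fold drop seen in 8 of 8 isolates. OAC1 (YKL120W), for a mitochondrial oxaloacetate and isopropylmalate carrier, fell by -1.41 (SE 0.20, adjusted p = 0.0435), a 2.66-fold drop also in 8 of 8. Genes of methionine and sulfur assimilation and of amino acid synthesis under Gcn4 were lower as lists, and ribosomal protein and ribosome biogenesis genes were higher, each with an adjusted p = 0.357 with an estimated correlation. The comparison asks which transcripts shifted while the strains evolved.

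Among the lists in that comparison, 22 of 23 methionine and sulfur genes were lower, with a median of -0.70 (camera adjusted p = 1.52e-15, and adjusted p = 0.357 with an estimated correlation). In it 17 genes were lower adjusted over the list alone and 0 over all genes, with MET2 at -1.22, MET5 at -1.27 and MET16 at -0.98. Of the Gcn4 list, 45 of 48 genes were lower, with a median of -0.41 (adjusted p = 1.52e-15, and adjusted p = 0.357 with an estimated correlation), 15 of them adjusted over the list alone. ILV2 stood at -1.07, ILV3 at -0.81 and BAT1 at -1.03, all in the branched-chain amino acid pathway. The iron regulon had 20 of 22 genes lower at a median of -0.33 (adjusted p = 8.68e-09, and adjusted p = 0.357 with an estimated correlation). Adjusted over the list alone, 10 of its genes were lower and 1 higher: the ferroxidase gene FET3 stood at -0.83, the heme oxygenase gene HMX1 at -0.70 and the reductase gene FRE1 at 0.55. The phosphate regulon had 17 of 18 genes lower at a median of -0.42 (adjusted p = 0.000772, and adjusted p = 0.578 with an estimated correlation), with 1 gene lower adjusted over the list alone, PHO8 at -0.70, PHO89 at -1.07 and VTC2 at -0.47. The induced environmental stress response had 29 of 40 genes lower at a median of -0.12 (adjusted p = 0.00395, and adjusted p = 0.670 with an estimated correlation), with 1 gene lower adjusted over the list alone, HSP26 at -0.78, HOR7 at -0.85 and HSP78 at -0.35.

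Ribosomal protein genes were higher in 134 of 138 cases at a median of 0.26 (camera adjusted p = 1.97e-22, and adjusted p = 0.357 with an estimated correlation), such as RPL8B at 0.34, RPS2 at 0.32 and RPL10 at 0.34. Ribosome biogenesis genes were higher in 98 of 101 cases at a median of 0.14 (adjusted p = 8.1e-14, and adjusted p = 0.357 with an estimated correlation), such as MAK5 at 0.30, UTP4 at 0.30 and ENP1 at 0.26. All 10 histone genes were higher at a median of 0.15 (adjusted p = 0.00661, and adjusted p = 0.455 with an estimated correlation), with HTA1 at 0.53, HTB2 at 0.28 and HHO1 at 0.15. Cell cycle and DNA replication genes were higher in 19 of 29 cases at a median of 0.03 (adjusted p = 0.0283, and adjusted p = 0.578 with an estimated correlation), with CLB6 at 0.27, RFA3 at 0.41 and RFA1 at 0.24. Not called were proteasome subunits at a median of 0.03 (adjusted p = 0.286), the ubiquitin system at -0.01 (0.810), chaperones at 0.07 (0.134), ergosterol at -0.06 (0.311), respiration at -0.02 (0.810), glycolysis at 0.00 (0.810) and hexose transporters at -0.02 (0.560). The same held for redox defence at -0.00 (0.976), a-specific genes at 0.05 (0.865), alpha-specific genes at -0.04 (0.865), mating genes at 0.04 (0.461), DNA damage at -0.02 (0.560) and cell wall at -0.05 (0.592). The loci engineered in other strains were not called: UBP6 stood at -0.08, RPN6 at 0.08, UBI4 at -0.32, LYS2 at -0.34, URA3 at 0.08, HIS3 at -0.58, CUP1-1 at 0.03 and CUP1-2 at 0.02.

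For evolved against parental strains, limma called 2 of 6252 genes, both lower, and 622 had an unadjusted p under 0.05. Each slide held both classes for 3 chromosomes on 7 arrays. On slide 1, 3 genes were called, LEU1 at -1.92, OAC1 at -1.31 and LEU2, named after its value was seen. On slide 2, limma called 0, with 613 under an unadjusted p of 0.05, and LEU1 stood at -1.93 and OAC1 at -1.51 (adjusted p = 0.405). The list medians on slides 1 and 2 were -0.69 and -0.64 for methionine and sulfur, 0.37 and 0.14 for ribosomal proteins, -0.22 and -0.47 for iron, 0.07 and 0.22 for ribosome biogenesis and 0.15 and 0.23 for histones. They were -0.08 and -0.72 for Gcn4 genes, -0.92 and 0.01 for the phosphate regulon and -0.04 and 0.14 for cell cycle genes. Respiration was called in opposite directions, at 0.12 with 30 of 43 genes higher (camera adjusted p = 0.00488) and -0.19 with 42 of 43 lower (3.15e-07), and so was redox defence, at 0.08 (0.0338) and -0.13 (0.00642). The stress response, at 0.09 (0.0694) and -0.42 (8.62e-12), and glycolysis, at 0.12 (0.0742) and -0.16 (0.000913), also turned in sign. Of the 7 and 14 list calls on slides 1 and 2, 0 held with an estimated correlation (smallest adjusted p = 0.592 and adjusted p = 0.248 with an estimated correlation). With 7 arrays on a slide that test could hardly call any list, so this outcome speaks neither for nor against the calls. No gene was called without the pairing by chromosome, with processed signals, without background subtraction or with the deposited ratios, and 255, 591, 618 and 591 then had an unadjusted p under 0.05. The LEU1 and OAC1 calls also ended without any 1 array other than the parental XI array or those of XVI, with LEU1 from -2.14 to -1.58 and OAC1 from -1.55 to -1.14.

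Parental disomes in batch differed from the wild type most at ADE1 (YAR015W), a purine synthesis gene, which rose by 4.66 (SE 0.52, adjusted p = 0.000626), 25.3-fold and in 6 of 6 strains. The labels give no genotype of the reference, and in DNA the ADE1 ratio of evolved isolates outside disome I had a median of 3.98 with the strain in Cy5 and -0.14 in Cy3, so that an effect of the extra chromosome on ADE1 cannot be read from this value. LYS2, for lysine synthesis, stood at 2.96 in 6 of 6 but was not called (limma adjusted p = 0.124). LYS2 and the other lysine synthesis genes have the same limit, since the labels give no genotype of the reference. Genes for chaperones were higher as a list, and those for ribosomal proteins and for the a mating type were lower, with an adjusted p = 0.422, 0.691 and 0.422 with an estimated correlation. This contrast asks what an extra chromosome does to the transcripts of all others, with the genes of the named chromosome left out.

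Of the chaperone list, 25 of 30 genes were higher in the parental disomes at a median of 0.24 (camera adjusted p = 0.000319, and adjusted p = 0.422 with an estimated correlation), with HSP26 at 0.72, HSP10 at 0.85 and HSC82 at 0.40. The stress response had 29 of 40 genes higher at 0.20 (adjusted p = 0.00924, and adjusted p = 0.691 with an estimated correlation), with TFS1 at 0.64 and HSP78 at 0.59. Gcn4 genes were higher in 33 of 48 cases at 0.17 (adjusted p = 0.0196, and adjusted p = 0.715 with an estimated correlation), with LYS4 at 0.95, LYS9 at 1.20 and ILV5 at 0.54, which stood at -0.23 against 0 in place of the control. Iron genes were higher in 18 of 22 cases at 0.29 (adjusted p = 0.00556, and adjusted p = 0.691 with an estimated correlation), with the siderophore transporter genes ARN1 at 0.29 and ARN2 at 0.70 and FRE3 at 0.38. Ribosomal protein genes were lower in 98 of 138 cases at -0.24 (adjusted p = 0.000202, and adjusted p = 0.691 with an estimated correlation), with RPL43B at -0.88, RPL23B at -1.01 and RPL17A at -0.49. Ribosome biogenesis genes were lower in 65 of 101 cases at -0.06 (adjusted p = 0.0196, and adjusted p = 0.715 with an estimated correlation), with UTP30 at -0.59, RRP7 at -0.39 and NOP56 at -0.48. Phosphate genes were lower in 15 of 18 cases at -0.70 (adjusted p = 0.00615, and adjusted p = 0.691 with an estimated correlation), with PHM6 at -1.93, PHO11 at -1.53 and PHO8 at -0.71. All 7 a-specific genes were lower at -0.56 (adjusted p = 0.00446, and adjusted p = 0.422 with an estimated correlation), with BAR1 at -0.75, MFA1 at -0.67 and AGA2 at -0.56. Haploid and mating genes were lower in 10 of 12 cases at -0.22 (adjusted p = 0.0219, and adjusted p = 0.422 with an estimated correlation), with FAR1 at -0.68, STE18 at -0.39 and FUS1 at -0.29. Histone genes were lower in 9 of 10 cases at -0.37 (adjusted p = 0.0149, and adjusted p = 0.691 with an estimated correlation), with HTZ1 at -0.48, HTB2 at -0.49 and HHT1 at -0.41.

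For parental disomes against wild type, limma called 1 of 6252 genes, and 108 had an unadjusted p under 0.05. No member of a list was called, and the block correlation within chromosomes was 0.243. UBP6 stood at 0.33, RPN6 at 0.18, UBI4 at 0.43, URA3 at 0.22, HIS3 at 0.44, CUP1-1 at 0.03 and CUP1-2 at 0.12. The control was 1 array on slide 1, assumed to vary like the other batch arrays, and each shift above includes that array's own deviation. Within that slide, with 8 arrays, ADE1 stood at 4.16 (limma adjusted p = 0.0191), and ribosomal proteins at -0.22 (camera adjusted p = 6.96e-07), chaperones at 0.20 (0.000942), a-specific genes at -0.66 (0.000942) and respiration at -0.14, with 36 of 43 lower (0.000942), were called. Of these 4 calls 0 held (smallest adjusted p = 0.620 with an estimated correlation). Biogenesis at 0.06, the stress response at 0.02, Gcn4 at -0.01, phosphate at -0.15, iron at 0.03, mating genes at -0.16 and histones at -0.25 were not. With processed signals limma called 0 genes, with 95 unadjusted, and with the disomes tested against 0 in place of the control it called 28 and the chaperone gene HSC82 stood at -0.00.

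Evolved disomes in batch, 8 isolates, were set against the same single wild-type array, so that this contrast is not independent of the one for parental disomes. ADE1 was higher by 4.53 (SE 0.51, limma adjusted p = 0.000775, 8 of 8 isolates), with the same limit from the reference genotype. LYS2 stood at 2.64 (limma adjusted p = 0.368), also with that limit. Chaperone genes were higher as a list, in 24 of 30 cases at 0.28 (camera adjusted p = 3.62e-07, and adjusted p = 0.281 with an estimated correlation), with HSC82 at 0.59, HSP60 at 0.67 and SSB1 at 0.47, which stood at -0.06 against 0 in place of the control. Methionine and sulfur genes were lower in 21 of 23 cases at -0.60 (adjusted p = 1.05e-06, and adjusted p = 0.454 with an estimated correlation), with MET2 at -1.26, MET5 at -1.31 and MET14 at -0.75. Phosphate genes were lower in 17 of 18 cases at -0.92 (adjusted p = 1.05e-06, and adjusted p = 0.454 with an estimated correlation), with PHO11 at -2.33, PHM6 at -2.33 and PHO8 at -1.36. All 7 a-specific genes were lower at -0.48 (adjusted p = 0.00638, and adjusted p = 0.454 with an estimated correlation), with STE6 at -0.55, MFA1 at -0.77 and BAR1 at -0.57. Gcn4 genes were lower in 33 of 48 cases at -0.26 (adjusted p = 0.0318, and adjusted p = 0.843 with an estimated correlation), with ILV3 at -0.74, TRP5 at -0.71 and ILV2 at -0.78. Ergosterol genes were lower in 19 of 24 cases at -0.13 (adjusted p = 0.0445, and adjusted p = 0.454 with an estimated correlation), with ERG26 at -0.50, ERG28 at -0.81 and ERG3 at -0.33. Ribosomal proteins were called higher at a median of 0.01 and a mean of 0.05 (adjusted p = 0.0445, and adjusted p = 0.843 with an estimated correlation), with RPL16B at 0.69, which stood at -0.12 against 0, RPS0A at 0.59 and RPL43B at -0.78.

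For evolved disomes against wild type, limma called 1 of 6252 genes, and 112 had an unadjusted p under 0.05. Within slide 1, ADE1 stood at 4.55 (limma adjusted p = 0.00655), and chaperones at 0.23 (camera adjusted p = 6.64e-05), ribosomal proteins at 0.15 (0.000262), methionine and sulfur at -0.41 (7.42e-08), phosphate at -1.07 (7.71e-10), a-specific genes at -0.56 (6.60e-05), ribosome biogenesis at 0.09 (0.0111) and glycolysis at 0.28 (0.00869) were called. Of these 7 calls 0 held (smallest adjusted p = 0.454 with an estimated correlation). Gcn4 at -0.09 and ergosterol at -0.11 were not. UBP6 stood at 0.22, RPN6 at 0.25, UBI4 at 0.10, URA3 at 0.04, HIS3 at -0.12, CUP1-1 at 0.05 and CUP1-2 at 0.14, not called. With processed signals limma called 0 genes, with 109 unadjusted, and against 0 in place of the control it called 230.

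In phosphate-limited chemostats, 12 evolved isolates differed from the wild type in 2446 of 5975 transcripts, with ribosome biogenesis genes higher and stress and glycolytic genes lower as lists, each with an adjusted p = 0.499 with an estimated correlation. ADE1 rose by 3.26 and LYS2 by 2.26, each in 12 of 12 isolates, both with the limit from the reference genotype given for batch. Among the highest of the other called genes were LYS20 by 1.20, LYS21 by 1.13, LYS4 by 1.02, LYS9 by 0.99, for lysine synthesis, ARG1 by 1.26, for arginine synthesis, and the asparagine synthetase gene ASN2 by 0.98. Since the labels give no genotype of the reference, an effect of the extra chromosomes on lysine synthesis cannot be read from these lysine genes. The high-affinity hexose transporter genes HXT7 and HXT6 rose by 2.29 and 2.28 in 10 of 12 isolates. HXT7 stood at -0.68 and -0.43 in the VIII isolates and at 2.89 in the parental disome V. Stress genes fell, DDR2 by -1.53, HSP12 by -1.52, YRO2 by -1.44 and PGM2 by -1.44, and so did HXT5 by -1.72 and PNS1 by -1.57. ASP3-1, of a cluster of asparaginase genes on chromosome XII, fell by -1.71 on average. It stood at -7.55 in X-14.2 and -6.65 in X-14.1 against -1.25 to -0.16 in the other 10 isolates. ASP3-2 at -1.69, ASP3-3 at -1.697 and ASP3-4 at -1.68 were called with it, and leaving out any 1 of 11 isolates ended these 4 calls, with ASP3-1 from -1.93 to -1.51.

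In the chemostat, 99 of 101 ribosome biogenesis genes were higher at a median of 0.37 (camera adjusted p = 1.76e-19, and adjusted p = 0.499 with an estimated correlation). Of these, 85 rose over all genes and 90 adjusted over the list alone, such as NOG1 at 0.57, NSR1 at 0.66 and UTP22 at 0.42. Of 48 Gcn4 genes, 39 rose and 1 fell, and 40 and 1 adjusted over the list alone, with a median of 0.53 and ARO2 at 0.96 (camera adjusted p = 3.79e-15, and adjusted p = 0.316 with an estimated correlation). The stress response fell in 27 of 40 genes, 30 adjusted over the list alone, at a median of -0.69 with HOR7 at -1.01 (camera adjusted p = 9.18e-09, and adjusted p = 0.499 with an estimated correlation). Of 21 glycolytic genes, 13 fell and 1 rose, and 15 and 1 adjusted over the list alone, at a median of -0.30 (camera adjusted p = 5.26e-05, and adjusted p = 0.499 with an estimated correlation). PGK1 fell by -0.99, TDH1 by -1.28 and TDH3 by -0.76. Iron genes fell in 10 of 21 cases, also 10 adjusted over the list alone, at -0.17 (camera adjusted p = 0.0155, and adjusted p = 0.499 with an estimated correlation), with ATX1 at -0.59, ARN2 at -0.32 and SMF3 at -0.31. Phosphate genes fell in 6 of 18 cases, 5 adjusted over the list alone, at -0.20 (camera adjusted p = 0.0462, and adjusted p = 0.831 with an estimated correlation), with PHM8 at -0.73, PHM6 at -0.84 and PHO81 at -0.35.

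Lists not called in the chemostat isolates were ribosomal proteins at a median of 0.02 (camera adjusted p = 0.343), the proteasome at -0.05 (0.441), with 5 members up and 10 down, the ubiquitin system at 0.05 (0.422) and chaperones at -0.06 (0.822). Methionine and sulfur stood at 0.09 (0.377), ergosterol at -0.08 (0.694), respiration at -0.17 (0.0559), redox defence at 0.03 (0.683), histones at -0.03 (0.933) and cell cycle at 0.05 (0.464). DNA damage stood at -0.08 (0.147), cell wall at -0.16 (0.147), a-specific genes at -0.38 (0.155), alpha-specific genes at -0.03 (0.822) and mating genes at -0.12 (0.464). Hexose transporters had a median of -0.19 and a mean of 0.09, of opposite sign (0.921). UBP6 fell by -0.32 (limma adjusted p = 0.00618) and RPN6 by -0.13 (0.00775), each in 12 of 12 isolates, and HIS3 rose by 0.54 (0.00609). URA3 stood at 0.25, UBI4 at 0.20, CUP1-1 at 0.48 and CUP1-2 at 0.47, not called. In the chemostat, limma called 1159 genes higher and 1287 lower, with 2350 in the same direction in at least 80% of isolates. The block correlation within chromosomes was 0.661, and 2844 genes were called with the slide as a random block. The reference was 1 control sample whose own spread is left out, so that a difference shared by all isolates is also a difference from that sample. All 12 isolates had the strain in Cy5 and no wild type was self-hybridised, so dye effects on single genes cannot be told apart here.

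**Figure D1:**
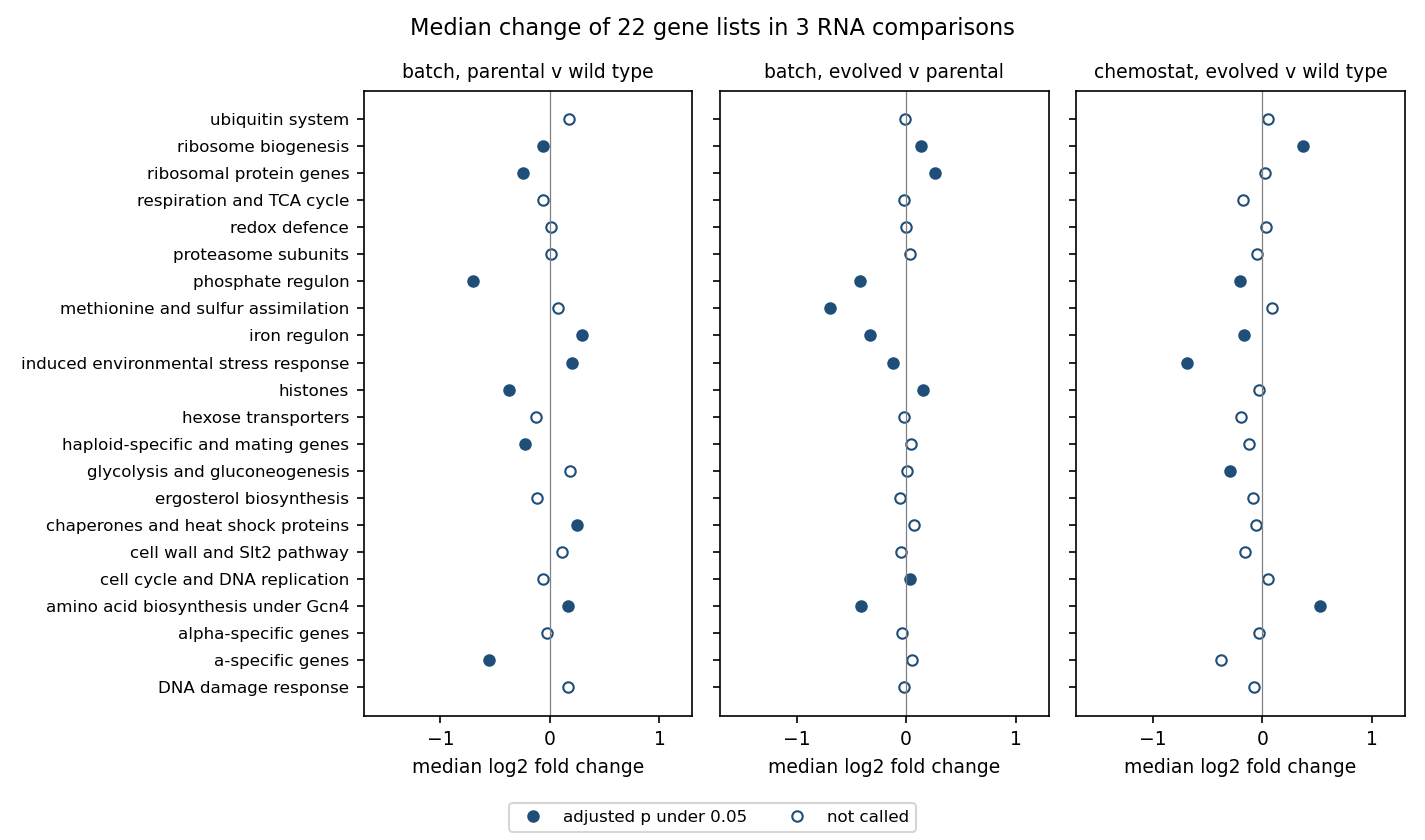
Median log2 fold change of the 22 tested gene lists in 3 RNA comparisons, parental disomes against wild type in batch, evolved against parental disomes in batch and evolved disomes against wild type in the chemostat; filled points have a camera adjusted p under 0.05 at the preset correlation and open points do not. Ribosome biogenesis stood at -0.06, 0.14 and 0.37 in these comparisons and the induced stress response at 0.20, -0.12 and -0.69, and 0 calls held with an estimated correlation.

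Evolved disome V isolates in the chemostat, 2 against the parental disome V, had higher ribosome biogenesis and Gcn4 transcripts and lower stress and cell wall transcripts as lists, each with an adjusted p = 0.558 with an estimated correlation. Biogenesis genes were higher in 97 of 101 cases at 0.33 (camera adjusted p = 3.45e-17, and adjusted p = 0.558 with an estimated correlation), with NOG1 at 0.57, BRX1 at 0.58 and YTM1 at 0.67. Gcn4 genes were higher in 47 of 48 cases at 0.42 (adjusted p = 1.32e-19, and adjusted p = 0.558 with an estimated correlation), 23 adjusted over the list alone, with ARO2 at 0.65 and ASN1 at 0.76. All 40 stress genes were lower at -0.51 (adjusted p = 3.24e-11, and adjusted p = 0.558 with an estimated correlation), 7 adjusted over the list alone, with CYC7 at -0.85, DDR2 at -0.94 and GDB1 at -0.44. Cell wall genes were lower in 15 of 17 cases at -0.20 (adjusted p = 0.000256, and adjusted p = 0.558 with an estimated correlation), 5 adjusted over the list alone, with CCW14 at -0.46 and GSC2 at -0.48. Respiration genes were lower in 33 of 43 cases at -0.16 (adjusted p = 0.00565, and adjusted p = 0.558 with an estimated correlation), 3 adjusted over the list alone, with ATP15 at -0.56, SDH1 at -0.43 and COX12 at -0.40. Iron genes were lower in 19 of 21 cases at -0.23 (adjusted p = 0.00923, and adjusted p = 0.703 with an estimated correlation), with SMF3 at -0.45, CCC2 at -0.45 and ATX1 at -0.34. Glycolytic genes were lower in 17 of 21 cases at -0.18 (adjusted p = 0.0494, and adjusted p = 0.699 with an estimated correlation), with TDH1 at -0.72, ENO1 at -0.46 and ADH1 at -0.42. Over all genes limma called 0 of 5955, 961 had an unadjusted p under 0.05, and 8, 12 and 6 were called with processed signals, without background subtraction and with the deposited ratios. The smallest p belonged to CDC60 at 0.62, SED1 at -0.97, WWM1 at 0.62, ARO3 at 0.71 and PPE1 at -0.57 (adjusted p = 0.109). Of the engineered loci, UBP6 stood at -0.43, RPN6 at -0.05, UBI4 at 0.49, URA3 at 0.13, HIS3 at 0.60, LYS2 at 0.33, CUP1-1 at 0.25 and CUP1-2 at 0.27, not called. The parental array is assumed to vary like the pairs of evolved isolates.

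Genes of the extra chromosome were expressed well above the others in parental and evolved strains alike. Their mean log2 ratio minus that of all other genes was 0.75 ± 0.06 (SD, n = 6) in the parental disomes in batch, a 1.68-fold level, and 0.77 ± 0.04 (SD, n = 8) in the evolved isolates, 1.71-fold. In the chemostat it was 0.66 ± 0.09 (SD, n = 12), 1.58-fold, from 0.39 in VIII-14.2 to 0.74, and 0.75 in the parental disome V. The evolved isolates differed from their parents by 0.03 ± 0.06 (SD, n = 6 chromosomes, 4 higher, exact two-sided p = 0.375), less than the spread, and the smallest p possible is 0.0313. Within slide 1 the difference was 0.06 (exact p = 0.5) and within slide 2 it was -0.00 (exact p = 1), each over 3 chromosomes with 0.25 as the smallest p.

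The list means of 6 isolates with both a batch and a chemostat array were compared, each as a ratio to the wild type grown in that condition. The ratio of stress response genes was higher in batch by 0.79, at -0.12 against -0.91, in 6 of 6 isolates, and the ratio of respiration genes was higher by 0.36, at 0.14 against -0.22, also in 6 of 6. The ratio of Gcn4 genes was lower in batch by -0.68, at -0.10 against 0.58, and that of phosphate genes by -0.83, at -1.18 against -0.36, with 0 of 6 isolates higher. Each has an exact two-sided p of 0.0313, the smallest possible, and 0 of 22 lists passed the correction (smallest adjusted p = 0.172). Array format and condition cannot be told apart, and no list was tested within a format. The isolates of a condition share its wild-type reference, so that a deviation of the reference would shift all 6 differences together. The test takes the isolates as independent, although V-14.1 and V-14.2 come from the same disome.

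DNA arrays asked whether each strain still held its extra chromosome. The named chromosome had a mean median ratio of 0.85 ± 0.21 (SD, n = 84 strains), a 1.80-fold level, where a second copy in a haploid strain would give a ratio near 1. The level depends on the processing, and with normexp on the mean signals it was 1.35. All other chromosomes stood at 0.00 ± 0.08 (SD, 1275 medians), and the largest chromosome median of the euploid strains was 0.28. The evolved isolates with 9 in their label had 0.89 ± 0.22 (n = 22), GFP strains 0.78 ± 0.16 (n = 12), UBP6del strains 0.95 ± 0.22 (n = 12), E256X strains 0.80 ± 0.16 (n = 10) and URA3 strains 0.70 ± 0.12 (n = 10). The rpn6 strains had 1.02 ± 0.06 (n = 4), ubp6CA strains 0.96 ± 0.04 (n = 3), and cup1-UBI4 strains 0.87 ± 0.01 with GFP (n = 3), 0.997 ± 0.05 labelled E256X (n = 2) and 0.97 ± 0.04 labelled delubp6 (n = 2, with the library labelled Dis V-delubp6-cup1-UBI4). Single strains stood at 0.93 for lys2, 0.77 for UBP6del-lys2, 0.91 for XI-14.1 and 0.06 for XII-14.2.

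**Figure D2:**
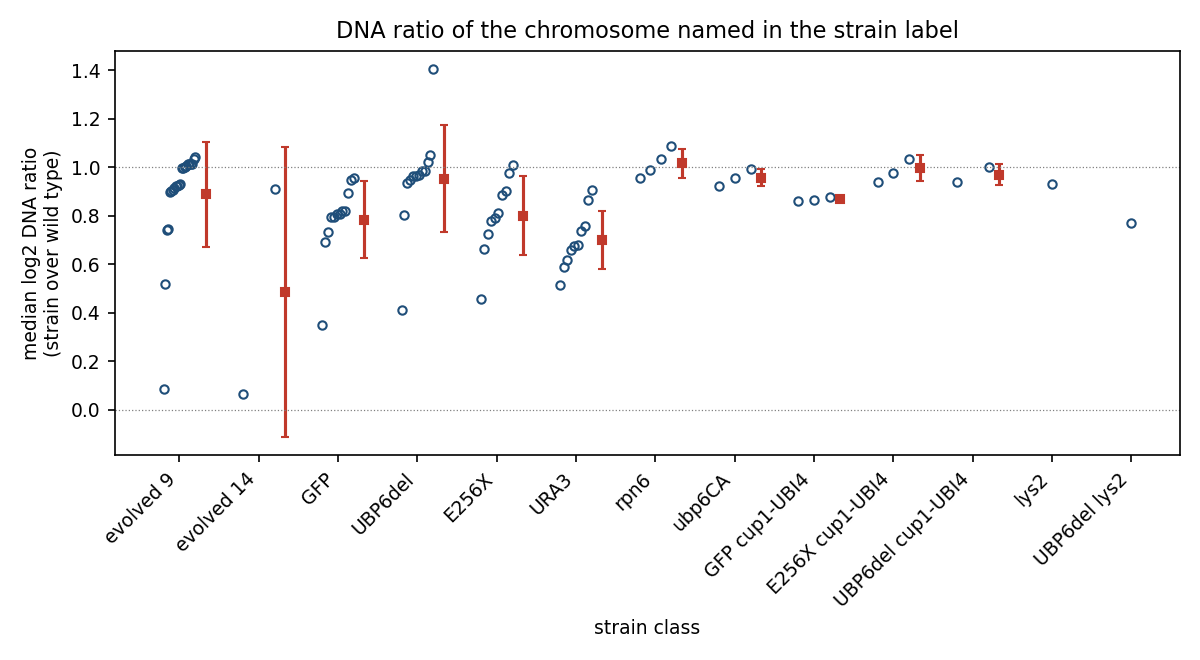
Median log2 DNA ratio, strain over wild type, of the chromosome named in the label, by strain class; open circles are arrays, red squares and bars are class means ± SD, and dotted lines mark 0 and 1. Most arrays sit near 1, and XII-9.1 at 0.08 and XII-14.2 at 0.06 sit at 0.

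Set against GFP strains of the same chromosome, the named chromosome was higher by 0.17 ± 0.26 (SD) in UBP6del strains, in 11 of 12 pairs (exact two-sided p = 0.0449, adjusted p = 0.180). The largest rises were in I, at 1.40 against 0.82, and VIII, at 0.98 against 0.35, while IV fell, at 0.41 against 0.79. Over the 8 pairs in the same dye, the UBP6del difference was 0.16, with 7 higher (exact two-sided p = 0.227, adjusted p = 0.667). The difference was 0.03 in E256X strains, with 6 of 10 pairs higher (exact p = 0.697), -0.09 in URA3 strains, with 3 of 10 higher (exact p = 0.148, adjusted p = 0.297), and 0.09 in evolved isolates, with 6 of 10 higher (exact p = 0.287, adjusted p = 0.383). None passed the correction over 4 comparisons. Within the slides that hold both UBP6del and GFP strains the difference was 0.01 on slide 14, 5 arrays against 1, and 0.28 on slide 16, 1 against 2. Evolved isolates were higher by 0.21 on slide 26, 3 against 1, and no slide held E256X or URA3 with GFP. These slide values mostly set different named chromosomes against each other. Slide 16 set II against IV and XII, slide 26 set I and II against V, and slide 14 had only XIII in both classes. On slide 26 the dye of the strain differed too.

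Of 85 disome arrays, 80 had the named chromosome gained. These include XIII-9.2 at 0.52, just past the threshold of 0.5, while XIII-9.1 stood at 0.90. They also include XV-9.1 and XV-9.2 at 0.74, where the right 205 genes of XV stood at -0.01 and -0.03. The named chromosome was intermediate in GFP VIII at 0.35, UBP6del IV at 0.41 and E256X XII at 0.46, and near 0 in XII-9.1 at 0.08 and XII-14.2 at 0.06. Among 1323 other chromosomes, 48 of them of the 3 euploid strains, 6 were gained, 0 lost and 33 intermediate, 4 of these in the euploid UBP6del strain. Chromosome II was gained whole in XV-9.2 at 0.88. The others were small chromosomes: VI at 0.55 in UBP6del I, I at 0.58, III at 0.50 and VI at 0.62 in URA3 II, and I at 0.58 in rpn6 VIII.

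Parts of chromosomes were gained in 4 evolved isolates, 2 of disome XII and 2 of disome XV, with levels like those of a whole extra chromosome. In XII-9.1 and XII-14.2, the left part of chromosome XII from YLL067C to AAT2 (95 genes) stood at 0.97 and 0.93. The rest of XII stood at -0.00 in XII-14.2, and in XII-9.1 it stood at 0.00 as far as YLR456W and at 1.24 over the last 11 genes, from NBP1 to YRF1-5. A break was also found at NBP1 in the euploid UBP6del strain and at YLR458W in the euploid GFP strain. The end of XII in XII-9.1 therefore cannot be read as a second gained part. XII-9.1 and XII-14.2 also carried the left part of XIII, from YML133C to PRP39 (96 genes), at 0.91 and 0.91. XV-9.1 carried the same part of XIII at 0.85 and the part of XV from YOL166C to THI72 (364 genes) at 0.88. XV-9.2 carried that part of XV at 0.86, the part of XIV from MDJ2 to CUS2 (43 genes) at 0.94 and the whole of II. A break at MDJ2, 10 genes from the left end of XIV, was also found in GFP I, II, IX, XI and XVI, E256X XIV, XIV-9.1 and XIV-9.2. A distance of 10 genes is the smallest that the segmentation allowed. Where this part of XIV starts is therefore uncertain. With ratios limited to ±1.5, a choice made after seeing the data, the part of XII ran 8 genes further, to MLH2 (103 genes), at 0.98 and 0.93. ADE16, the next gene after AAT2, stood from -3.62 to -1.35 on all 6 XII arrays. Among these is XII-9.2, which had no step there, so that the end at AAT2 may rest on this 1 low gene. Smaller steps were found in GFP IX, on VII from COS12 to HAP2 (28 genes) at 0.37, and in GFP XIV, on IV to YDL228C (23 genes) at 0.39. In total 238 breaks were found in 57 of 88 arrays, 228 of them within 20 genes of an end, 106 of these in GFP disomes, and 10 further inside in 6 arrays.

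**Figure D3:**
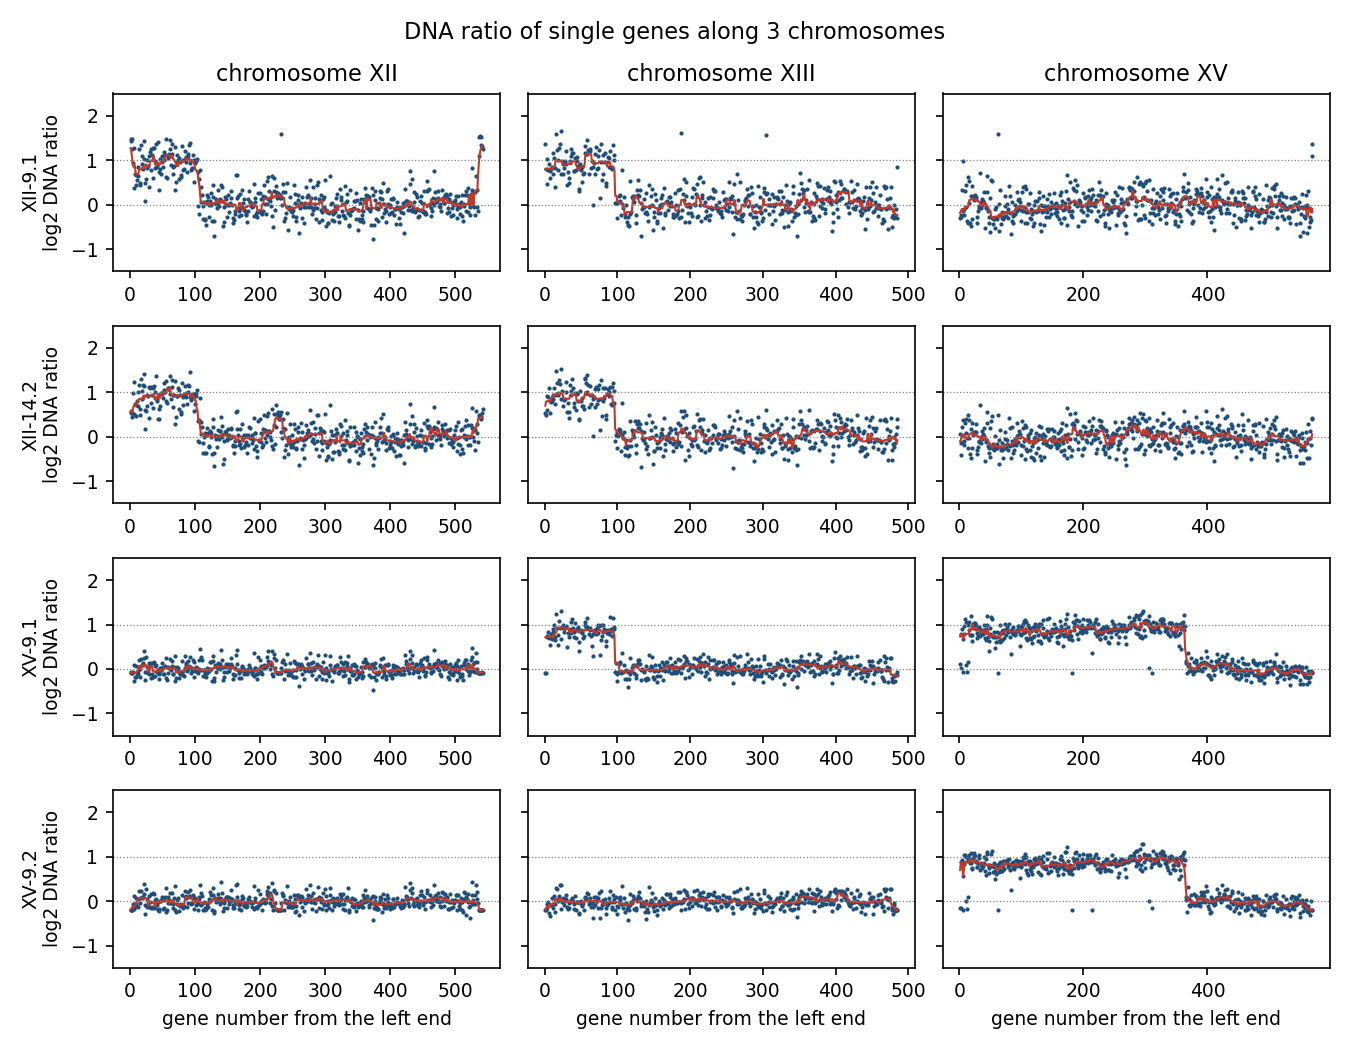
Log2 DNA ratio of each gene, as points, with a running median in red, along chromosomes XII, XIII and XV in the isolates XII-9.1, XII-14.2, XV-9.1 and XV-9.2; the horizontal axis is the gene number from the left end and the vertical axis is limited to -1.5 to 2.5. The left 96 genes of XIII stand at 0.91 in XII-9.1 and XII-14.2 and at 0.85 in XV-9.1.

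The UBP6 gene had lost DNA signal in strains labelled UBP6del and also in those labelled E256X. It stood at -2.30 ± 0.83 (SD, n = 16, from -3.04 to 0.38) in UBP6del strains against -0.36 in all others (n = 71), a difference of -1.94 (two-sided permutation p = 1e-05, the smallest these resamples can give, adjusted p = 7e-05). In the library labelled Dis V-delubp6-cup1-UBI4 it stood at 0.38. In the libraries labelled E256X, UBP6 stood at -1.90 ± 0.67 (SD, n = 13, from -2.81 to -0.76) against -0.02 in strains with neither label (n = 58), a difference of -1.88 (two-sided permutation p = 1e-05, also the smallest), a test added after the values were seen. The ubp6CA strains had -0.02 ± 0.09 (SD, n = 3). On slide 14, UBP6 was lower in UBP6del than in GFP strains by -2.55, and on slide 16 by -3.28. For the other engineered loci no difference between their class and all other arrays passed the test: RPN6 by -0.18 (adjusted p = 0.419, permutation test), URA3 by -0.08 (0.913), LYS2 by -0.22 (0.419, from -0.594 to 0.155 when 1 of the 2 strains was left out), UBI4 by 0.16 (0.419), CUP1-1 by 0.03 (0.913) and CUP1-2 by 0.03 (0.913).

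**Figure D4:**
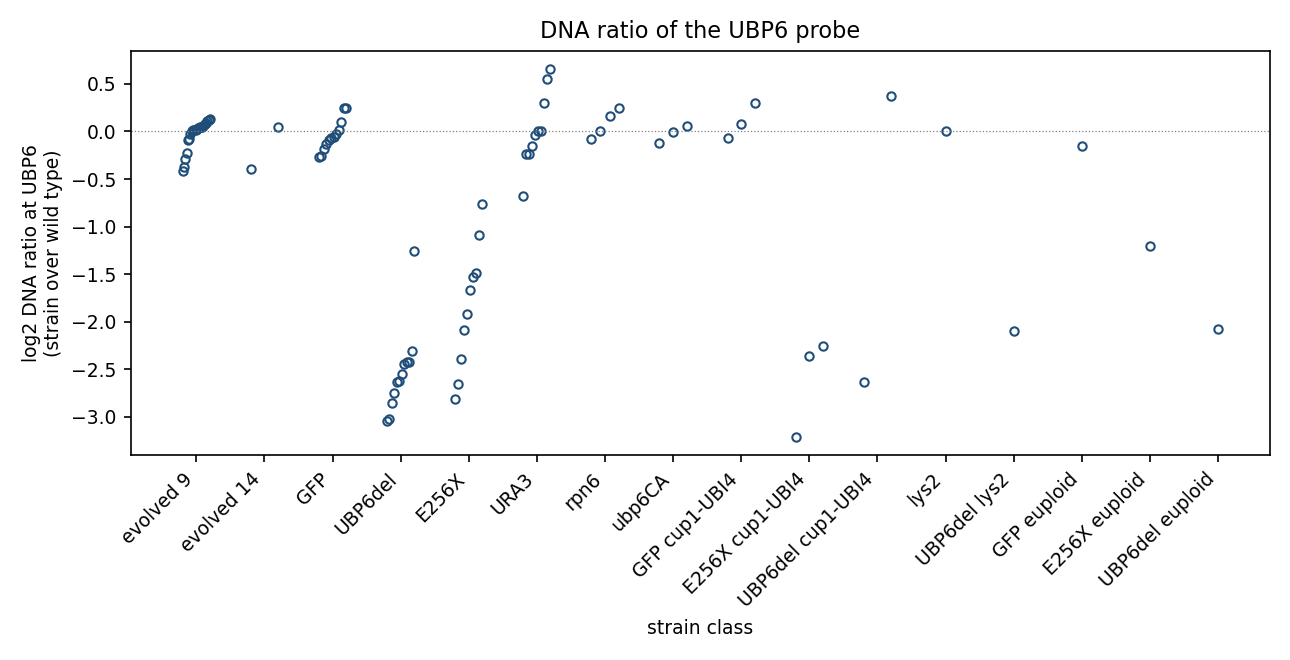
Log2 DNA ratio of UBP6, strain over wild type, with 1 point per array, by strain class and with the 3 euploid strains. UBP6del strains average -2.30 and E256X strains -1.90, while ubp6CA strains average -0.02.

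Gene by gene, the DNA of UBP6del strains differed from that of GFP strains at UBP6 (YFR010W) alone, where it was lower by -2.41 (SE 0.16, limma adjusted p = 1.79e-07, 13 of 13 strains). In the libraries labelled E256X it was also UBP6 alone, lower by -1.78 (SE 0.24, adjusted p = 0.0143, 11 of 11 strains). This comparison asks for further loci that differ in dose between the classes. Of the other engineered loci with UBP6del, LYS2 stood at -0.06, RPN6 at -0.13, URA3 at -0.10, UBI4 at -0.02, CUP1-1 at -0.52 and CUP1-2 at -0.61. With E256X, LYS2 stood at -0.02, RPN6 at -0.05, URA3 at -0.17, UBI4 at -0.07, CUP1-1 at -0.76 and CUP1-2 at -0.75. Without a term for the dye, 538 genes were called for UBP6del and 975 for E256X. An unadjusted p under 0.05 was found for 831 genes with UBP6del and 891 with E256X, and with a term for array format limma called 0 for E256X (UBP6 at -1.86, adjusted p = 0.2002), with 577 unadjusted. No slide held E256X and GFP strains together.

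Evolved isolates with 9 in their label, 20 against 10 GFP strains, differed in 3543 genes, 1912 higher and 1631 lower, mostly by little: the median size was 0.22, and 220 reached 0.5. The highest were AIF1 at 0.95, ECL1 at 0.76, YDR157W at 0.72, ASC1 at 0.71 and ALT2 at 0.61. The lowest were YFL067W at -1.49, YER138W-A at -1.31, YLR162W at -1.31, YEL076C-A at -1.31 and YLR464W at -1.29. YDR157W and these lowest reading frames have no symbol beside their systematic name. YFL067W, YEL076C-A and YLR464W lie near chromosome ends, where GFP disomes had 106 breaks and evolved isolates with 9 had 36. Whether these breaks bear on their values was not tested. Of the engineered loci, URA3 was lower by -0.27 (limma adjusted p = 0.000265), CUP1-1 by -0.82 (0.000628), CUP1-2 by -0.85 (0.000351) and RPN6 by -0.14 (0.0105), and UBI4 was higher by 0.17 (0.0257). UBP6 stood at 0.02 and LYS2 at 0.02. From 42.6% to 65.5% of the genes of each nuclear chromosome were called. On slide 26, which holds both classes, only 26.9% of 3091 genes called without that slide differed in the same direction, and the strain's dye also differs between the classes there. Without the chromosome block 1773 were called and with the slide as a random block 1111.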

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

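The tests of the chromosome parts, of the slide for mitochondrial DNA and of relabelled arrays were chosen after the results were seen, while those of the slide and GC content for evolved isolates and of GC content for mitochondrial DNA were chosen before.

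Gains of chromosome parts were found in the evolved isolates XII-9.1, XII-14.2, XV-9.1 and XV-9.2, all on slide 24. For the parts of XII, XIII and XV, a fault of the slide is argued against by its other arrays, XII-9.2 and URA3 XV. Their largest step at these breaks was 0.0268, and steps on the 84 arrays without these gains ran from -0.11 to 0.15. The break of XIV in XV-9.2 was not compared with other arrays. DNA of a XII isolate in XV-9.1, which shares the part of XIII at 0.85, is argued against by the left part of XII, which stood at -0.0219 in XV-9.1. With ratios as measured, 3 of 4 breaks lay within 1 gene, a distance chosen after the breaks were seen, of a reference gene without a probe, YML045W, YNL284C-B and YOR192C-B, against 606 of 5721 positions for such genes of any length (exact one-sided p = 0.00436) and 120 for those of at least 3000 bases (exact one-sided p = 3.55e-05). These 3 are reading frames of Ty retrotransposons, so that recombination between Ty copies might be a source of the breaks, a hypothesis found on these breaks that the arrays cannot test further, and selection for losing the rest of XII or XV stays open and untested.

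The 3543 genes whose DNA differed between evolved isolates and GFP strains were spread over all nuclear chromosomes. A GC trend as the whole cause is argued against, since 3382 genes were called after it was taken out of each array, 2857 of them shared with the first count. On slide 26, with GFP V and the evolved isolates I-9.1, II-9.1 and II-9.2, the differences of genes called without that slide correlated at -0.280 with their fitted change across 3091 genes, which are not independent replicates. Differences between slides, or between the dye orientations there, are therefore a candidate explanation for much of the count. Relabelling arrays within chromosomes gave as many genes in 1 of 100 cases, the real one, with 0 as the highest of the others. Only slide 26 held both classes, so that these relabelings cannot tell the classes from the slides. Real dose differences between the strains stay open.

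Mitochondrial DNA ratios lay far from 0, with a mean of 1.23 ± 1.25 (SD, 88 arrays), 51 arrays over 1 and 2 under -1, and the highest was 3.82, in XI-9.1. Low GC content of the probes as the whole cause is argued against by the 9 of 23 probes with a GC content of at least 35%, as in 99.8% of nuclear probes, which had a mean of 1.06. Slides held 84.6% of the variance (permutation p = 1e-05, the smallest these resamples can give, and 95% of permutations lay under 42.3%), so that a difference in reference DNA or preparation between slides is a candidate explanation. In classes of at least 4 strains, means ran from -0.57 ± 0.60 in rpn6 to 1.86 ± 0.61 in UBP6del strains, but classes and slides overlap. A change of mitochondrial copy number in the strains stays open and untested.

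For evolved against parental disomes in batch, 2 of 100 relabelings within chromosomes gave at least the real 2 genes, the real one included. Another gave 69, which points to a structure of the arrays other than the classes, so that these relabelings cannot exclude chance. For UBP6del against GFP strains, 2 of 100 gave at least the real 1 gene, and the highest of the others was 759, which points to such a structure too. For the libraries labelled E256X, 6 of 100 gave at least the real 1 gene, with 203 as the highest of the others, so that chance is not excluded for a count of 1 gene as such. That gene is UBP6, lower by -1.78 in 11 of 11 strains, and these relabelings do not test it by name: its own difference of -1.88 had a permutation p of 1e-05, the smallest these resamples can give.

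Among 55 groups of 4 to 10 arrays, 3 held a value far from the others, and chance gives about 1 in 20 groups, or 2.75 here. The mitochondrial DNA ratio was -0.458 in E256X XIV, and the nearest of the 10 E256X strains stood at 1.17. The mean of the hexose transporters was -0.384 in the parental disome VIII, and the nearest of 6 stood at 0.0759. The mean of the cell cycle list was -0.228 in VIII-14.1, and the nearest of 8 evolved isolates stood at -0.0576.

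Arrays outside the comparisons held signals larger in size than those of the controls. In the deposited ratios without a scanner file, chromosome VI stood at -0.907 in IV-9.1 and -0.903 in IV-9.2, whose chromosome IV stood at 0.03 and 0.01. Without a scanner file, neither the sign of these ratios nor the chromosome in the label could be checked. Chromosome V stood at 0.881 in V-9.1 and 0.890 in V-9.2. The RNA of chromosome XVI in XVI-14.2, whose labels contradict each other on the dye, stood at 0.740 when read as Cy5 over Cy3, and the largest chromosome value of the wild-type array was 0.0561. As the mean of its genes minus that of all others, it stood at 0.745 there, 0.743 in the parental disome XVI and 0.761 in XVI-14.1. These values argue against the strain in Cy3 on this array, a reading that turns the sign.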

How the results depend on the processing

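Leaving out each array in turn for RNA counts, leaving out the Dis V-delubp6-cup1-UBI4 array or the arrays with over 40% of spots removed, adding pairs of breaks and limiting ratios to ±1.5 were chosen after seeing the data. Over 260 results and 2812 alternative values, 2771 kept their direction and 2606 also their side of the threshold or their size. These totals include the setting of the brightest probe, which could change nothing. Among single genes and lists, 98 values were weaker, 19 stronger and 36 reversed. The chemostat count kept its size, from 1742 with the genes of the named chromosome kept to 3168 with isolates taken as independent, and 2205 to 2454 when each isolate was left out. The count for UBP6del was 1 in each alternative except that without a dye term. Green signal over background was lowest, at 3.68, on a 15k DNA array and at 5.64 on a 15k RNA array, which limits what dim genes can show there. Taking the brightest probe changed no gene value in these comparisons and so tests nothing, and slide as a block could not be fitted for evolved against parental disomes, where chromosomes lie within slides. Unless stated, the cause was not tested.

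For evolved against parental disomes, 2 genes became 0 with processed signals, without background subtraction, with deposited ratios, without the chromosome block and with XVI-14.2 in Cy3, with 591, 618, 591, 255 and 390 genes at an unadjusted p under 0.05 in limma, and the cause was not tested. With XVI-14.2 in Cy5, the reading its chromosome XVI RNA argues for, 3 genes were called. LEU1 and OAC1 were kept among them, and 753 genes had an unadjusted p under 0.05. Leaving out 1 array gave 0 to 3 genes. With XVI-14.2 in Cy3, HHO1 stood at -0.000225, CUP1-1 at -0.0468 and CUP1-2 at -0.0535, and the disomic chromosome difference at -0.0979 (exact p = 0.781). In that setting the sign of a whole disome array is turned, which by construction moves the disomic chromosome. Leaving out 1 array gave URA3 from -0.128 to 0.197, CUP1-1 from -0.141 to 0.186 and CUP1-2 from -0.144 to 0.176.

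For parental disomes against wild type, 1 gene became 0 with processed signals (95 unadjusted) and 28 against 0. CUP1-1 and CUP1-2 reversed to -0.211 and -0.0271 with processed signals and to -0.212 and -0.0285 with deposited ratios. Against 0, HSC82 stood at -0.00244, ILV5 at -0.230, URA3 at -0.288, UBP6 at -0.0737, CUP1-1 at -0.0946 and CUP1-2 at -0.0982. For evolved disomes, 1 gene became 0 with processed signals (109 unadjusted), 0 with XVI-14.2 in Cy3 (95) and 230 against 0. With XVI-14.2 in Cy5 the count stayed at 1 (118 unadjusted). CUP1-1 reversed to -0.155 with processed signals, -0.156 with deposited ratios and -0.00507 with XVI-14.2 in Cy3. Against 0, RPL16B stood at -0.121, SSB1 at -0.0605, URA3 at -0.467, UBP6 at -0.181, CUP1-1 at -0.0769, CUP1-2 at -0.0741 and UBI4 at -0.162, and URA3 at -0.00505 with isolates as independent. The cause was not tested, though against 0 the spread of the single control is left out by construction.

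For disome V in the chemostat, 0 genes became 8 with processed signals, 12 without background subtraction and 6 with deposited ratios, and with slide as a block RPN6 stood at 0.0177, CUP1-1 at -0.158 and CUP1-2 at -0.117. The 39 gene list calls became 0 with an estimated correlation.

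With normexp on the DNA arrays, the named chromosome stood at 1.35 over all strains, 1.55 in evolved isolates with 9, 1.24 in E256X, 1.40 in GFP, 1.61 in UBP6del, 1.07 in URA3 and 1.29 in ubp6CA strains, and with cup1-UBI4 at 1.21 with UBP6del, 1.01 with GFP and 1.60 with E256X. GFP cup1-UBI4 strains stood at 0.876 when centred outside the named chromosome and 0.835 with means, and ubp6CA at 0.919 with means. E256X minus GFP reversed to -0.116 with normexp, -0.00359 with means and -0.0432 with pairs in the same dye. Gained other chromosomes went from 6 to 10 with normexp, and by construction to 14 at a threshold of 0.3 and 1 at 0.7. Breaks went from 238 to 28 with 20 genes on each side, and inner breaks from 10 to 24 with pairs of breaks, both by construction. LYS2 in lys2 strains ran from -0.594 to 0.155 when 1 of 2 strains was left out. Without a dye term, 538 genes were called for UBP6del and 975 for E256X, and with a format term 0 for E256X (577 unadjusted). The evolved count with 9 fell to 1773 without the chromosome block and 1111 with slide as a random block, and the cause was not tested.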

Other observations

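No tests were run on the values in this part, which were all chosen after they were seen.

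In 4 disome series a gene on the extra chromosome had a low DNA ratio on every array of the series. URA2 stood at -3.15 and -3.03 in both X isolates, ADE16 from -3.62 to -1.35 in 6 XII strains, LEU9 from -2.82 to -2.10 in 6 XV strains and MET12 from -4.00 to -1.05 in 6 XVI strains, while their medians on all other arrays were -0.02, -0.05, -0.03 and 0.01. These genes act in pyrimidine, purine, leucine and one-carbon metabolism. The 10 genes from ASP3-1 to SHH4 on XII, which begin with the asparaginase cluster, stood at -3.37 and -3.14 in X-9.1 and X-9.2, the DNA arrays of the disome whose chemostat isolates had ASP3-1 RNA at -7.55 and -6.65. A segment of XII that ended at YLR161W stood at -0.94 in URA3 VIII, from GID11, and at -0.74 in URA3 XI, from YLR152C, lower than the rest of XII by -0.74 and -0.70.

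ADE1 DNA differed between dye orientations among evolved isolates, but it was low in both orientations in the engineered disome I and euploid strains. Among evolved isolates with 9 outside disome I, it was over 1 in 8 of 8 arrays with the strain in Cy5, with a median of 3.98 and a range of 3.28 to 4.47, and in 0 of 12 with the strain in Cy3, with a median of -0.14 and a range of -0.28 to -0.01. In disome I it stood at -3.73 with E256X in Cy5, and at -3.45 with GFP, -1.17 with UBP6del and -3.89 with URA3 in Cy3. In I-9.1 and I-9.2, both in Cy5, it stood at 1.49 and 2.12. In the euploid strains it stood at -4.60 with E256X in Cy5, and at -3.57 with GFP and -2.70 with UBP6del in Cy3.

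Marker genes set some arrays apart from others of their strain label. The Cy3 array of E256X-cup1-UBI4 XI had URA3 at 3.45 and TRP1 at 1.88, and the Cy5 array of that label had ADE1 at 3.48 and LEU2 at 3.14. The library labelled Dis V-delubp6-cup1-UBI4, whose UBP6 stood at 0.38, had URA3 at 3.73 and TRP1 at 2.10. URA3 stood at -3.13 in UBP6del-lys2 V and at 1.71 in lys2 V, where LYS2 stood at -0.52.

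Small chromosomes were above 0 together on several arrays and below 0 in UBP6del-lys2 V, where I stood at -0.44 and VI at -0.32. In the euploid UBP6del strain, I stood at 0.26, III at 0.22, VI at 0.28 and IX at 0.22. In UBP6del I, III stood at 0.45, VI at 0.55 and IX at 0.32 while XII stood at -0.26, and in URA3 II, I stood at 0.58, III at 0.50, VI at 0.62 and IX at 0.40 while XII stood at -0.43. In GFP XII, I stood at 0.36, III at 0.32, VI at 0.38 and IX at 0.28, and in rpn6 VIII at 0.58, 0.37, 0.40 and 0.25.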
